A study of Mus musculus with 12 samples.

How the data were processed

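Gene expression was measured in B cells from the spleens of female C57BL/6 mice that were wild type (WT) or lacked microRNA-155 (miR-155 KO). Per the labels, the cells were resting conventional B cells taken on day 0, 3 or 6 of infection with Plasmodium berghei ANKA, a rodent malaria parasite, and enriched with a magnetic negative-selection kit. Total RNA was extracted on columns with DNase digestion and labelled with Cy3 by a low-input one-colour protocol, per the labels' protocols. Each of the 12 samples was hybridised to 1 Agilent mouse array, and the 6 groups of genotype and day held 2 arrays each. The labels do not say that the replicates of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

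Per the file headers, the arrays were scanned in 1 colour and read with Agilent Feature Extraction 10.5.1.1, with probe positions on the mouse genome build mm9. The deposited scanner files hold intensity values on a linear scale for 45018 spots, of which 43379 were not controls. The processed signal had its background subtracted and spatial trends removed by the scanner software, and was not scaled between arrays, per the file headers. The series' deposited value table held the same intensity: it differed from the processed signal of the same array by 0 at every spot. Its scale is therefore linear and it is not centred. The median of its columns was 69.77 and 62.0 for WT day 0 replicates 1 and 2, 59.95 and 68.47 for KO day 0, 47.58 and 54.8 for WT day 3, 44.91 and 60.17 for KO day 3, 46.44 and 52.83 for WT day 6, and 53.51 and 66.64 for KO day 6.

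The processed signal was taken to log2 and each array's 75th percentile over spots that were not controls was subtracted. Spots marked by the scanner software as outliers were left out (106 to 666 per array), and the spots of a probe were averaged, giving 41174 probes. No spot was saturated. Probes well above background on both arrays of at least 1 group were kept (25677). Where a gene had several kept probes (6034 genes), the probe with the highest mean signal over the 12 arrays stood for it. This gave 16598 genes or transcripts.

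Probe names were updated through a reference table of mouse genes (no genome or transcript sequence was used): 27479 probes were named through an accession, 5478 through a current symbol and 679 through an older symbol, and 7538 kept the name in the file. Of the 16598 genes or transcripts, 13205 had a current symbol and 3393 kept the name in the file. The array had 0 probes named for the miR-155 host gene, so the genotype labels could not be checked on the targeted gene.

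Differences between groups were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. All 12 arrays entered 1 model with a coefficient per group, so the 6 groups shared 1 estimate of spread. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p under 0.05 are called changed. Errors are standard errors (SE) of the log2 difference from this model, with n = 2 arrays per group unless said otherwise. All p-values are two-sided. The 12 comparisons were the 3 pairs of days within each genotype, KO minus WT on each day and averaged over the days, and the difference between the genotypes in the day 3 and day 6 responses. For a gene not well above background on either array of 1 group, a bound is given as "at least N-fold". The mean of the brighter group was set against a floor for the dimmer group, the mean over its arrays of the higher of the gene's own value and the lowest value among probes well above background on that array. This was judged only on the probe that stood for the gene.

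Gene lists were tested with limma's camera, which asks whether the genes of a list move more one way than all other genes. The inter-gene correlation was preset at 0.01, each test was repeated with a correlation estimated from the data, and p-values were adjusted over the lists within a comparison. The 27 lists covered type I interferon response, interferon-gamma response, MHC class I, MHC class II, B cell activation, germinal centre, plasma cell, unfolded protein response, cell cycle, glycolysis, oxidative phosphorylation, ribosome biogenesis, B cell identity, follicular B cells, marginal zone B cells, B-1 cells, B cell cytokines, apoptosis, immediate early and heat shock genes, published miR-155 targets, and markers of erythroid cells, T cells, NK cells, monocytes and macrophages, neutrophils, dendritic cells and platelets. A gene that a list named by 2 symbols was counted once, a correction made after the results were seen. Of the 12 comparisons, no list call held with an estimated correlation. A test of genes with miR-155 sites in their 3' untranslated regions had been planned and was not run, since no transcript sequences were used here.

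The groups, the comparisons, the lists, the alternatives and the rule for naming genes were chosen before the data were examined. The rule named, per comparison, the changed genes with a proper symbol whose arrays did not overlap between the groups, up to 10 with the largest rise and 10 with the largest fall. For the average over days the day means had to differ the same way on all 3 days, and for a difference in response no such condition was set. Where fewer than 5 genes changed, all that changed and the 5 with the lowest p were named. The rule also named up to 4 changed members of each list, or 2 with the lowest p where none changed, and in the genotype comparisons Spi1, Socs1, Inpp5d and Jarid2 among others. The text gives a selection of these, and the results of some named genes are not reported here.

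The 12 arrays lay on 3 slides of 4. Slide 1 held WT day 3 replicate 2, both WT day 6 arrays and KO day 0 replicate 1. Slide 2 held replicate 1 of WT day 0 and WT day 3 and replicate 2 of KO day 0 and KO day 3. Slide 3 held WT day 0 replicate 2, KO day 3 replicate 1 and both KO day 6 arrays. Each comparison was refitted with the slide as a block, and differences were also taken between the arrays of 1 slide where a slide held both groups. No slide held both groups of WT day 6 against day 0, KO day 6 against day 0 or KO against WT at day 6.

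The alternatives were normexp background correction of the mean and local background signals (offset 50), quantile normalization, no filter on dim probes, the deposited value table, the mean of all kept probes of a gene, slide as a block, replicate number as a block, and leaving out each array in turn. Added after seeing the data were the fits without the day 3 arrays, with and without the slide block, normexp with bright local backgrounds replaced, and the genotype average over days 0 and 6.

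The signal's 75th percentile lay between 578 and 959.6. The fit was tested on simulated data for 16312 genes with the real spread pooled over groups and 100 genes changed per size. Real replicates differed more at day 3, so the counts below may not hold. For WT day 6 minus day 0 it recovered 25 of 100 genes changed by 1 on the log2 scale and 87 of 100 changed by 2, with 4 false calls. For KO minus WT at day 6 it recovered 26 and 85, with 1 false call, and for the genotype average over days 76 and 98, with 8 false calls. With the slide as a block it recovered 0 and 7 for WT day 6 minus day 0, 0 and 0 for KO minus WT at day 6, and 42 and 91 for the average over days.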

Results

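The series measured transcripts in splenic B cells of WT and miR-155 KO mice before infection (day 0) and on days 3 and 6 of Plasmodium berghei ANKA infection, a model of severe malaria. miR-155 is a microRNA induced in activated lymphocytes that represses the transcripts it binds. The design asks how the B cell transcriptome responds and how this differs without miR-155. The 12 arrays in 6 groups of 2 limit the precision, and 16598 genes or transcripts were measured. Values are log2 signals scaled to each array's 75th percentile, and differences are log2 values ± SE.

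The replicates of a group correlated at 0.993 (WT day 0), 0.991 (KO day 0), 0.975 (WT day 3), 0.978 (KO day 3), 0.991 (WT day 6) and 0.993 (KO day 6) across genes, which are not independent replicates. Between the 2 replicates, 1718 genes differed by at least 2-fold at WT day 3 and 1302 at KO day 3, against 350 to 534 genes in the other 4 groups. On the first principal component, which held 43.6% of the variance, the 4 day 0 arrays lay between -50.5 and -43.6 and the 4 day 6 arrays between 37.4 and 62.2. The day 3 arrays lay apart within each genotype: WT replicates 1 and 2 at -31.4 and 22.8, and KO replicates 2 and 1 at -27.7 and 23.1. Both day 3 arrays nearest day 0 were on slide 2, so slide and time course position cannot be separated from these 4 arrays alone.

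**Figure D1:**
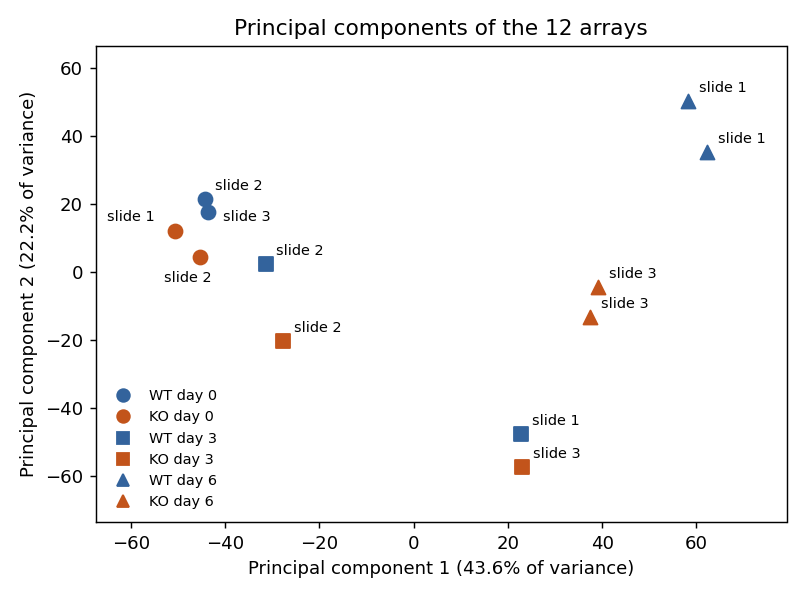
First (43.6% of variance, x axis) and second (22.2%, y axis) principal components of the 12 arrays over all genes, with colour for genotype, symbol for day and the slide beside each point. On the first component the day 0 arrays lie lowest and the day 6 arrays highest, and the replicates of each day 3 group lie more than 50 units apart.

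In WT B cells at day 3, interferon-induced genes lay higher than at day 0 as a group, but only Chst1 changed over all genes. That count rests on replicates far apart (type I interferon medians 1.16 and 4.26). Chst1, a Golgi sulfotransferase, fell by 1.60 ± 0.148 (SE, n = 2 per group, adjusted p = 0.0445), to 32.9% of its day 0 signal. Irf1, a transcription factor of the interferon response, was 1.54 ± 0.222 higher (adjusted p = 0.23) and Socs1, an inhibitor of interferon signalling, 2.21 ± 0.593 higher (0.249). Neither passed.

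Of 29 interferon-gamma genes 0 changed over all genes and 20 rose with p adjusted over the list alone. 27 were positive and the median was 1.56 (camera adjusted p = 3.49e-14, and 0.607 with an estimated correlation). All 45 type I interferon genes were positive with a median of 1.74 (adjusted p = 4.43e-14, and 0.607 with an estimated correlation), but 0 passed either adjustment. Of 23 MHC class I genes, which load and present peptides, 9 rose with p adjusted over the list alone and 0 over all genes, with a median of 0.63. Cell cycle (66 of 69 positive, median 0.78), oxidative phosphorylation (44 of 46, 0.36) and ribosome biogenesis (36 of 36, 0.44) lay higher by camera with adjusted p = 1.69e-08, 1.05e-07 and 6.77e-07, each 0.607 with an estimated correlation, and held 0 changed genes in either adjustment. B cell cytokines (median 0.49, 7 of 20 risen over the list alone) and glycolysis (0.45) lay higher, and B cell identity (-0.18) and follicular B cell genes (-0.42) lower, with adjusted p between 0.0109 and 0.0383 (0.607 with an estimated correlation). Markers of NK cells and T cells had medians of 0.29 and 0.25 (adjusted p = 0.056 and 0.0881).

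Under the slide block the medians were 1.46 for interferon-gamma, 1.54 for type I interferon, 0.60 for MHC class I and 0.77 for the cell cycle, and the T cell median turned to -0.21. Within slide 2 they were 0.93, 0.51, 0.32, 0.11 and -0.32. Chst1 was at -1.57 with the block (adjusted p = 0.258) and at -1.48 within the slide. In limma 2711 genes had an unadjusted p under 0.05. The slide block gave 0 changed genes (2673 unadjusted), as did keeping dim probes. The block ended the cytokine, glycolysis, B cell identity and follicular calls (camera adjusted p = 0.0541 to 0.169). Without WT day 3 replicate 1 the interferon-gamma, type I interferon, MHC class I, cell cycle, glycolysis, ribosome biogenesis and B cell identity medians were 2.61, 3.08, 1.05, 1.40, 0.86, 0.76 and -0.35. Without replicate 2 the type I interferon, MHC class I, oxidative phosphorylation and cytokine medians were 0.46, 0.27, 0.19 and 0.30. The calls then ended for the cell cycle (0.13, camera adjusted p = 0.9), ribosome biogenesis (0.07, 0.457), glycolysis (0.09, 0.734), B cell identity (-0.08, 0.425) and follicular genes (-0.23, 0.264). The follicular median was -0.34 (0.0531) without WT day 0 replicate 1.

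By day 6, 4576 genes had changed in WT B cells, 2315 upward and 2261 downward, and genes of cell division were the largest risen group. Of 69 cell cycle genes 60 rose and 0 fell over all genes (65 rose with p adjusted over the list alone), with a median of 2.10 and 68 positive. Ccnb1 and Ccnb2, which drive entry into mitosis, rose 9.5-fold (3.25 ± 0.585, SE, n = 2 per group, adjusted p = 0.00624) and 7.85-fold (2.97 ± 0.408, 0.00241). Of 35 plasma cell genes 18 rose and 2 fell (23 and 3 over the list alone, median 0.84), among them Sdc1 (CD138, a plasma cell surface marker, 1.78 ± 0.381) and Prdm1 (its master regulator, 1.72 ± 0.288). Ighg3, the IgG3 heavy chain constant region, rose by 3.98 ± 0.365 (adjusted p = 0.000734).

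Of 34 genes of the unfolded protein response 15 rose and 2 fell (17 and 2 over the list alone, median 0.54), with Xbp1, a regulator of secretory capacity, at 1.42 ± 0.211. Of 46 oxidative phosphorylation genes 16 rose and 0 fell (17 over the list alone, median 0.58) and of 20 glycolysis genes 11 rose and 1 fell (12 and 1, median 0.70), with Ldha at 1.29 ± 0.366. Interferon-gamma genes rose in 13 of 29 and fell in 0 (15 and 1 over the list alone, median 1.39), led by the GTPases Iigp1 (4.85 ± 1.06) and Gbp2 (2.53 ± 0.699), MHC class I genes rose in 4 of 23 (4 over the list alone, median 0.60) and ribosome biogenesis genes in 4 of 36 (1 over the list alone, median 0.37). Of 45 type I interferon genes 1 rose and 1 fell (0 over the list alone, median 0.59, adjusted p = 0.286). The camera adjusted p was 1.23e-17 for the cell cycle, 1.69e-05 for plasma cell genes, 0.000465 for the unfolded protein response, 7.83e-06 for oxidative phosphorylation, 0.0187 for glycolysis, 2.08e-05 for interferon-gamma, 0.00131 for MHC class I and 0.00522 for ribosome biogenesis. With an estimated correlation it was 0.585 for plasma cell genes and 0.646 for the other 7.

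Of 30 B cell identity genes 3 rose and 15 fell (4 and 17 over the list alone, median -0.52, adjusted p = 0.00043, and 0.594 with an estimated correlation), among them Spib (-1.30 ± 0.205) and Cd72 (-1.26 ± 0.157). Of 22 marginal zone genes 1 rose and 12 fell (2 and 13 over the list alone, median -0.89, adjusted p = 0.000635, and 0.646), with Cr2, a complement receptor, at -2.62 ± 0.29 and S1pr3, a receptor that holds cells in the marginal zone, at -3.06 ± 0.472. Fcer2a (CD23, a follicular B cell receptor for IgE) fell to 4.49% of its day 0 signal (-4.48 ± 0.654, adjusted p = 0.00302). 1 of 12 follicular genes rose and 4 fell (the same counts over the list alone, median -0.43, adjusted p = 0.0575). Of 39 B cell activation genes 3 rose and 14 fell (3 and 20, median -0.49, adjusted p = 0.00522, and 0.535) and of 20 immediate early and heat shock genes 1 rose and 13 fell (1 and 13, median -0.87, adjusted p = 0.000294, and 0.535), with Egr3 at -1.79 ± 0.293 and Atf3 at -2.38 ± 0.301. The germinal centre list split into 7 risen and 8 fallen of 21 (7 and 8 over the list alone, adjusted p = 0.821). Il4 and Lta fell and Il10 and Cxcl10 rose among 20 cytokine genes (3 rose and 6 fell in both adjustments, adjusted p = 0.239).

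Markers of other cells moved alongside these groups. Of 21 dendritic cell markers 0 rose and 16 fell in both adjustments (median -0.99, adjusted p = 1.07e-05, and 0.585 with an estimated correlation), Siglech and Clec9a at least 8.19-fold and 7.66-fold. NK cell markers fell in 10 of 22 and rose in 2 (11 and 2 over the list alone, median -0.65, adjusted p = 0.0474, and 0.646), Ncr1 at -2.11 ± 0.245 but Gzmb, a cytotoxic granule protease, at 5.20 ± 1.07. Monocyte and macrophage (0 rose and 7 fell of 35 in both adjustments, median -0.58) and erythroid markers (2 and 3 of 24, -0.67) lay lower and platelet markers higher (5 and 0 of 16, 0.87), with adjusted p = 0.0187, 0.0389 and 0.0187 (0.646 with an estimated correlation). The largest rises measured on both days were Speer6-ps1 (55.6-fold), Gzmb (36.7-fold) and Iigp1 (28.8-fold), and the largest falls Apol7c, to 2.23%, and the chemokine receptor Ccr3, to 2.91%. Saa3, an acute phase protein, and Esm1 were at least 55.5-fold and 47.1-fold higher.

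No slide held both groups. With slide blocked 364 genes changed, 346 of them among the 4576. The SE grew 1.44-fold, the cell cycle, plasma cell, B cell identity and dendritic cell medians were 1.75, 0.98, -0.48 and -0.93, the interferon-gamma and marginal zone medians 0.60 and -0.28, and those of type I interferon and T cells (0.05 without the block) turned to -0.26 and -0.58. The block ended interferon-gamma, glycolysis, MHC class I and ribosome biogenesis calls (camera adjusted p = 0.0672 to 0.271). Keeping dim probes gave 2941 genes. The platelet median was 0.16 without WT day 6 replicate 1 and 1.46 without replicate 2. The NK call ended without WT day 0 replicate 1 (-0.53, 0.0525) or WT day 6 replicate 1 (-0.49, 0.2), and the erythroid call without replicate 2 of either day (-0.51 and -0.51, 0.0817 and 0.191). The monocyte call ended without WT day 0 replicate 2 (-0.56, 0.0817) and that of ribosome biogenesis without WT day 6 replicate 2 (0.24, 0.068), where the unfolded protein response stood at 0.36.

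Between days 3 and 6, 3104 genes changed in WT B cells, 1506 upward and 1598 downward. Of 35 plasma cell genes 22 rose and 1 fell (26 and 1 over the list alone, median 0.97): Sdc1 rose by 2.68 ± 0.381 (SE, n = 2 per group, adjusted p = 0.00314) and Prdm1 by 1.67 ± 0.288. Ighg3 rose 28.8-fold. Of 69 cell cycle genes 17 rose (23 over the list alone, median 1.25, all 69 positive), with Ccna2, a cyclin of DNA replication, at 2.17 ± 0.518, and of 34 unfolded protein response genes 12 rose (15 over the list alone, median 0.41). Ccnd1, the G1 cyclin D1, fell to 12.6% of its day 3 signal, and Cd40, the receptor for T cell help, to 36.2%.

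All 45 type I interferon genes were negative (median -1.20) and 3 fell (1 over the list alone), while interferon-gamma genes had 1 risen and 1 fallen of 29 (1 and 0, median -0.41). B cell activation genes fell in 17 of 39 (20 over the list alone, median -0.60), marginal zone genes in 10 of 22 with 1 risen (12 and 2, -0.81), B cell identity genes in 8 of 30 with 2 risen (12 and 3, -0.41), MHC class II genes in 3 of 15 with 1 risen (6 and 1, -0.28), cytokines in 7 of 20 (8 fell and 1 rose, -0.54) and immediate early and heat shock genes in 6 of 20 (6 fell and 1 rose, -0.54). The camera adjusted p was 4.43e-09 for plasma cell genes, 8.35e-12 for the cell cycle, 0.00048 for the unfolded protein response, 1.74e-05 for type I interferon, 0.318 for interferon-gamma, 3.33e-05 for B cell activation, 0.00048 for the marginal zone, 0.00821 for B cell identity, 0.0322 for MHC class II, 0.00217 for cytokines and 0.000642 for immediate early genes. With an estimated correlation these adjusted p were 0.36, 0.668, 0.597, 0.836, 0.914, 0.216, 0.597, 0.597, 0.512, 0.517 and 0.461. Dendritic cell markers fell in 11 of 21 (12 fell and 1 rose over the list alone, median -1.05, adjusted p = 1.74e-05, and 0.512 with an estimated correlation) and NK markers in 9 of 22 (10 and 1, -0.56, 0.000642, and 0.597). Of 16 platelet markers 2 rose (2 over the list alone, 0.56, 0.0152, and 0.789).

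With the slide as a block 1805 genes changed, 1663 of them shared, and slide 1 held WT day 3 replicate 2 and both day 6 arrays. The cell cycle, plasma cell, type I interferon, B cell activation and dendritic cell medians were 0.95, 1.06, -1.75, -0.60 and -0.98 with the block and 0.59, 1.08, -2.47, -0.57 and -0.84 within slide 1. Leaving out WT day 6 replicate 1 or 2 gave 1153 and 2002 genes, and keeping dim probes 1761. Without WT day 3 replicate 2 the type I interferon median was -0.07 (camera adjusted p = 0.779) and the interferon-gamma median 0.53. The cytokine and platelet medians were then -0.20 and 0.28 (0.095 and 0.103), and the cell cycle median 1.89. Without WT day 3 replicate 1 the B cell identity and MHC class II medians were -0.17 and -0.29 (0.163 and 0.105), and the cytokine, marginal zone and platelet medians -0.82, -0.41 and 0.86. Without WT day 6 replicate 1 the platelet and MHC class II medians were 0.07 and -0.28 (0.671 and 0.0999), and without replicate 2 1.05 and -0.42.

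In KO B cells 7 genes changed between day 0 and day 3, 2 upward and 5 downward. Irf1 rose by 2.15 ± 0.222 (SE, n = 2 per group, adjusted p = 0.0154), a 4.44-fold rise. Olfr1008, an olfactory receptor gene, was at least 3.27-fold higher at day 3, when it was first well above background (adjusted p = 0.00936). Cttnbp2, which encodes a cortactin-binding protein, and Tbpl2, a TATA-box binding protein relative, fell at least 3.07-fold and 3.97-fold (adjusted p = 0.00245 and 0.0101), and Cpne4 and Olfr695 at least 2.25-fold and 1.44-fold (0.0154 and 0.0101).

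Interferon genes again lay higher as groups. Of 29 interferon-gamma genes 1 rose over all genes (Irf1) and 27 with p adjusted over the list alone (median 2.36, camera adjusted p = 4.13e-21, and adjusted p = 0.517 with an estimated correlation). Of 45 type I interferon genes 37 rose over the list alone and 0 over all genes (median 2.15, adjusted p = 5.12e-17, and 0.517 with an estimated correlation). MHC class I (16 of 23 risen over the list alone, median 0.78) and oxidative phosphorylation (25 of 46, 0.56) had adjusted p = 1.62e-11 and 7.04e-13 (0.517 with an estimated correlation). The cell cycle (67 of 69 positive, median 1.03, adjusted p = 4.08e-12, and 0.552 with an estimated correlation) and ribosome biogenesis (35 of 36, 0.55, adjusted p = 8.62e-09, and 0.536) held 0 changed genes. Socs1 was 4.08 ± 0.593 higher, Ifi47, an interferon-induced GTPase, 3.03 ± 0.606 higher and Ifng 2.07 ± 0.262 higher, with adjusted p = 0.0926, 0.134 and 0.0589. NK cell markers lay higher with these groups (8 of 22 risen over the list alone, median 0.66, adjusted p = 0.000102, and 0.517 with an estimated correlation). B cell cytokines (0.43), glycolysis (0.39) and the unfolded protein response (0.22) had adjusted p = 0.000567, 0.00673 and 0.0121 (0.517, 0.536 and 0.596 with an estimated correlation).

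Under the slide block the medians were 2.55 for interferon-gamma, 2.43 for type I interferon, 1.03 for the cell cycle, 0.72 for NK cells and 0.71 for T cells. Within slide 2 they were 2.28, 1.46, 0.39, 0.51 and 0.54. The block gave 12 changed genes, 4 of them shared with the 7, and Irf1 stood at 2.23 with it (adjusted p = 0.0997) and at 2.25 within the slide. In limma 3754 genes had an unadjusted p under 0.05. Without KO day 0 replicate 1, KO day 3 replicate 1 or KO day 3 replicate 2 there were 45, 15 and 13 changed genes. The cell cycle median was 0.39 without KO day 3 replicate 1 and 1.68 without replicate 2. Without replicate 1 the NK cell, glycolysis and oxidative phosphorylation medians were 0.41, 0.22 and 0.33, and the call for the unfolded protein response ended (0.18, camera adjusted p = 0.0788).

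In KO B cells 1767 genes changed between day 0 and day 6, 896 upward and 871 downward, again with cell division in front. Of 69 cell cycle genes 59 rose and 0 fell (68 over the list alone), with a median of 2.55 and all 69 positive. Ube2c, of the anaphase-promoting machinery, rose 9.9-fold (3.31 ± 0.562, SE, n = 2 per group, adjusted p = 0.0188). Of 29 interferon-gamma genes 11 rose and 0 fell (22 over the list alone, median 1.55), including Iigp1 (5.51 ± 1.06) and Cxcl9 (3.13 ± 0.559), a chemokine that draws T cells. Of 35 plasma cell genes 12 rose and 1 fell (18 and 2 over the list alone, median 0.39), with Fkbp11 at 1.96 ± 0.265.

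The unfolded protein response rose in 7 genes and fell in 1 of 34 (14 and 1 over the list alone, median 0.52), with Manf at 1.33 ± 0.304. Oxidative phosphorylation rose in 8 of 46 (32 over the list alone, 0.68), with Ndufa8 at 1.32 ± 0.229. Glycolysis rose in 2 of 20 (8 over the list alone, 0.60). MHC class I and type I interferon genes each rose in 1 gene (1 and 0 over the list alone, medians 0.57 and 0.99) and ribosome biogenesis in 0 of 36 (0 over the list alone, 0.37). The camera adjusted p was 3.58e-29 for the cell cycle, 7.37e-10 for interferon-gamma, 2.02e-05 for plasma cell genes, 2.16e-05 for the unfolded protein response and 4.56e-12 for oxidative phosphorylation (each 0.528 with an estimated correlation), 0.00753 for glycolysis and 3.05e-05 for MHC class I (both 0.611), 0.00224 for type I interferon (0.741) and 3.05e-05 for ribosome biogenesis (0.634).

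Among genes of resting B cells, 0 of 30 identity genes rose and 2 fell (0 over the list alone, median -0.05, adjusted p = 0.418), and 1 of 22 marginal zone genes rose and 4 fell (3 and 9 over the list alone, median -0.55, adjusted p = 0.01, and 0.634 with an estimated correlation), with Asb2 at -1.73 ± 0.347. Immediate early and heat shock genes fell in 9 of 20 and rose in 1 (the same over the list alone, median -0.53, adjusted p = 0.000385, and 0.528). The germinal centre list had 8 risen and 0 fallen of 21 (8 and 1 over the list alone) and a median of -0.20 although camera placed it upward (adjusted p = 0.257). Dendritic cell markers fell in 6 of 21 (8 over the list alone, median -0.65, adjusted p = 5.48e-05, and 0.528), erythroid markers in 8 of 24 (9 over the list alone, -0.97, 7.27e-05, and 0.582), with Ahsp, which stabilises haemoglobin, at least 5.61-fold lower. T cell markers rose in 3 of 27 (3 over the list alone, median 0.50, adjusted p = 0.0151, and 0.691), including Icos (1.85 ± 0.367), and monocyte and macrophage markers rose in 1 of 35 and fell in 2 (0 and 2 over the list alone, -0.53, 0.0139, and 0.675). Saa3 (78-fold), the chemokine Ccl8 (33.1-fold) and Gzmb (26.4-fold) had large rises, and the complement component C6 fell to 3.94% and Ccr3 to 4.25%.

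No slide held both groups. With slide blocked 0 genes passed in limma (lowest adjusted p = 0.055, 2843 genes at an unadjusted p under 0.05) with an SE 1.44-fold as large. The cell cycle, interferon-gamma, plasma cell, dendritic cell, erythroid and T cell medians were 2.15, 1.86, 0.36, -0.57, -0.47 and 1.23. The block ended erythroid and monocyte calls (camera adjusted p = 0.0837 and 0.531). Keeping dim probes gave 273 genes, and a fit without day 3 arrays, chosen after seeing the data, 4898. The T cell median was 0.21 without KO day 0 replicate 2 (camera adjusted p = 0.342), 0.78 without replicate 1 and 0.37 without KO day 6 replicate 1 (0.058). The last setting also ended the calls for marginal zone (-0.53, 0.0702) and monocyte and macrophage genes (-0.38, 0.0692).

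The WT and KO responses at day 6 shared no arrays. They had 642 risen genes in common, against 125 for independent lists of the same size, and 468 fallen genes, against 118.7. In all, 11 genes changed in both genotypes but in opposite directions. Across all genes, which are not independent replicates, the 2 responses correlated at 0.658.

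In KO B cells 296 genes changed between days 3 and 6, 128 upward and 168 downward. Of 21 germinal centre genes 5 rose and 0 fell (7 over the list alone, median 0.50), including Mef2b, a transcription factor of that programme, at 1.75 ± 0.329 (SE, n = 2 per group). Of 35 plasma cell genes 5 rose (12 rose and 1 fell over the list alone, median 0.48), with Fkbp11 at 2.22 ± 0.265. Of 69 cell cycle genes 1 rose over all genes, Cenpa, and 37 over the list alone (median 1.36, all 69 positive). Ccl8 rose 47.7-fold and Cxcr3, a chemokine receptor of activated lymphocytes, 6.1-fold, while Apol7c fell to 7.61%.

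Type I interferon genes (median -1.20, 1 of 45 positive) had 0 changed in either adjustment, and interferon-gamma genes 1 risen and 2 fallen of 29 (1 and 3 over the list alone, -0.97), with Irf1 at -1.21 ± 0.222 and Ido1, a tryptophan-degrading enzyme, at 3.15 ± 0.341. Immediate early and heat shock genes fell in 4 of 20 (10 over the list alone, -0.48), B cell activation genes in 0 of 39 (10 over the list alone, -0.35), and cytokines in 3 of 20 (6 fell and 2 rose, -0.43). NK markers fell in 4 of 22 (12 fell and 1 rose, -0.72), erythroid markers in 4 of 24 (12 over the list alone, -0.83) and dendritic cell markers in 2 of 21 (5 over the list alone, -0.63). The camera adjusted p was 0.000429 for germinal centre, 6.36e-09 for plasma cell, 3.74e-22 for cell cycle, 6.36e-09 for type I interferon, 1.29e-05 for interferon-gamma, 2.64e-06 for immediate early, 0.000429 for B cell activation, 0.000939 for cytokine, 2.56e-07 for NK, 3.63e-07 for erythroid and 9.59e-06 for dendritic cell genes. With an estimated correlation these adjusted p were 0.156, 0.194, 0.443, 0.629, 0.629, 0.156, 0.156, 0.38, 0.38, 0.429 and 0.38. MHC class I (-0.19), marginal zone (-0.34) and unfolded protein response genes (0.23) had 0 changed in either adjustment and adjusted p = 0.0092, 0.0326 and 0.00119 (0.811, 0.732 and 0.629 with an estimated correlation). Neutrophil granule genes Ctsg and Prtn3 rose by 3.39 ± 0.677 and 2.79 ± 0.488, 2 of 25 in that list (4 rose and 1 fell over the list alone, median 0.04, adjusted p = 0.669).

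With the slide as a block 41 genes changed, 37 of them shared, and slide 3 held KO day 3 replicate 1 and both day 6 arrays. The cell cycle, plasma cell, germinal centre, type I interferon and erythroid medians were 1.04, 0.43, 0.68, -1.57 and -0.56 with the block and 0.71, 0.49, 0.72, -1.86 and -0.33 within slide 3. Leaving out KO day 3 replicate 1 gave 496 genes, KO day 3 replicate 2 gave 59, KO day 6 replicate 1 or 2 gave 27 and 31, and keeping dim probes gave 84. Without KO day 3 replicate 1 the type I interferon median was -0.64 (camera adjusted p = 0.00534), the germinal centre median 0.24 (0.0279) and the erythroid median -1.49. The dendritic cell median was -0.40 without replicate 2. The MHC class I call ended without KO day 3 replicate 1 (0.01, 0.677), and the marginal zone call without KO day 3 replicate 2 or KO day 6 replicate 1 (0.237 and 0.267).

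Before infection 25 genes differed between KO and WT, 16 higher and 9 lower in KO. Cbr1, a carbonyl reductase encoded on chromosome 16, the chromosome of the miR-155 gene, was 1.81 ± 0.166 higher (SE, n = 2 per group, adjusted p = 0.00528). Nmrk1, a nicotinamide riboside kinase, was 1.97 ± 0.198 higher (0.00978) and Pltp, the phospholipid transfer protein, 1.42 ± 0.182 higher (0.0261). Tmem254a, Tspoap1, Nin and Gfi1, a transcriptional repressor, were lower in KO with differences of -1.76 ± 0.149, -1.58 ± 0.185, -1.56 ± 0.171 and -1.30 ± 0.171 (adjusted p = 0.00439, 0.0171, 0.0134 and 0.0296). Tbpl2, Ppef2, Letm1, Fn3krp and Cttnbp2 were at least 3.44-fold, 2.87-fold, 2.77-fold, 2.7-fold and 2.66-fold higher in KO, and Igf2bp3 and Aloxe3 at least 5.42-fold and 1.51-fold lower.

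Of the genes fixed for the genotype comparisons, Spi1, a transcription factor and published miR-155 target, was 0.76 ± 0.174 higher (adjusted p = 0.185, n = 2 per group), and Socs1, Inpp5d and Jarid2 were at -0.48, 0.01 and -0.26 (adjusted p = 0.791, 0.988 and 0.71). The 35 published miR-155 targets had a median of -0.04, with 0 changed over all genes or over the list alone (adjusted p = 0.422). Markers of T cells (median -0.56, 2 of 27 positive, adjusted p = 0.000208) and NK cells (-0.41, 3 of 22, 0.000217) and the cell cycle list (-0.39, 3 of 69, 0.000217) lay lower in KO, each 0.947 with an estimated correlation. Platelet markers (median 0.51, 15 of 16 positive, adjusted p = 0.00763, and 0.947 with an estimated correlation) and MHC class II genes, which present peptides to T cells (0.17, 14 of 15, 0.00197, and 0.611), lay higher. No gene of these 5 lists passed over all genes. Over the list alone 2 MHC class II genes were higher and 1 NK marker lower. B cell cytokines (-0.25) and plasma cell genes (-0.14) lay lower with adjusted p = 0.0197 and 0.0484 (0.947 with an estimated correlation).

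Under the slide block the T cell, NK cell, cell cycle, platelet and MHC class II medians were -0.94, -0.40, -0.42, 0.73 and 0.27, and within slide 2 -1.25, -0.53, -0.41, 0.71 and 0.24. The block called 6, 5 of them shared, with Cbr1 at 1.95 (adjusted p = 0.0482). In limma 2239 genes had an unadjusted p under 0.05. Leaving out KO day 0 replicate 1, KO day 0 replicate 2, WT day 0 replicate 1 or WT day 0 replicate 2 gave 57, 12, 6 and 14 genes. The T cell median was -0.18 without WT day 0 replicate 1 (camera adjusted p = 0.374), -1.04 without replicate 2 and -0.34 without KO day 0 replicate 2 (0.112). The platelet call ended without the first and the last of these arrays (0.40 and 0.34, 0.0662 and 0.075). The cytokine call ended without KO day 0 replicate 2 (-0.23, 0.0729), and the plasma cell call without replicate 2 of either genotype (-0.11 in WT and -0.06 in KO, 0.112 and 0.121).

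At day 3, 23 genes differed between KO and WT, 13 higher and 10 lower in KO, several of which also differed at day 0. Cbr1 was 1.93 ± 0.166 higher (SE, n = 2 per group, adjusted p = 0.00623), Nmrk1 1.86 ± 0.198 higher, Fam177a 1.49 ± 0.182 higher and Chst1 1.21 ± 0.148 higher (adjusted p = 0.0233, 0.0276 and 0.0276). Tmem267, Tmem254a, Tspoap1 and Nin were at -2.33 ± 0.308, -1.68 ± 0.149, -1.42 ± 0.185 and -1.40 ± 0.171 in KO. Olfr1008, Prune2 and Ppef2 were at least 4.25-fold, 4.72-fold and 2.27-fold higher and Slc9b2 at least 2.17-fold lower.

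All 29 interferon-gamma genes were positive in KO minus WT with a median of 0.97 (camera adjusted p = 5.25e-16, and adjusted p = 0.735 with an estimated correlation), but 0 changed over all genes or over the list alone. The same held for type I interferon (median 0.73, 43 of 45 positive, adjusted p = 1.15e-06, and 0.774 with an estimated correlation), MHC class I (0.33, 22 of 23, 2.69e-06, and 0.774), MHC class II (0.17, 15 of 15, 0.000328, and 0.422), platelet markers (0.56, 16 of 16, 0.000328, and 0.774) and erythroid markers (0.26, 17 of 24, 0.0215, and 0.774). T cell markers lay lower (-0.61, 1 of 27 positive, adjusted p = 3.03e-10, and 0.735), as did cell cycle genes (-0.18, 10 of 69, 0.0215, and 0.807). Immediate early and heat shock genes (0.07, 12 of 20, 0.00969, and 0.735) and ribosome biogenesis genes (0.13, 31 of 36, 0.0483, and 0.807) lay higher. In these 4 lists 0 changed over all genes, and 3 immediate early genes rose over the list alone. Socs1 was 1.39 ± 0.593 higher, and Spi1, Inpp5d and Jarid2 were at 0.10, 0.15 and -0.06, all 4 with adjusted p = 1.0. The 35 published miR-155 targets had a median of 0.06, 22 positive and 0 changed in either adjustment (adjusted p = 0.113).

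With slide blocked the medians were 1.27 for interferon-gamma, 0.88 for type I interferon, 0.08 for MHC class II and -0.09 for T cells. Within slide 2 they were 1.63, 1.31, 0.05 and -0.37. The block ended the MHC class II, T cell, cell cycle (-0.16) and immediate early (0.14) calls (adjusted p = 0.0791, 0.289, 0.289 and 0.0826). It left 0 genes in limma (lowest adjusted p = 0.095, 1003 at an unadjusted p under 0.05, against 666 without it), with Cbr1 at 1.79 (adjusted p = 0.101). Leaving out KO day 3 replicate 2 or WT day 3 replicate 1 gave 3 and 9 genes, and keeping dim probes 5. The interferon-gamma median was 0.11 without WT day 3 replicate 1 (camera adjusted p = 0.156) and 1.86 without replicate 2. Without replicate 1 the type I interferon and MHC class I medians turned to -0.58 and -0.03, and the erythroid median was 0.15 (0.0755). Without WT day 3 replicate 2 the MHC class II, platelet and erythroid calls ended (0.10, 0.27 and 0.07, with 0.14, 0.285 and 0.16), and the T cell median was -0.41. Without KO day 3 replicate 1 the type I interferon and MHC class I medians were 0.10 and 0.05 (0.632 and 0.296). Without KO day 3 replicate 2 the erythroid median turned to -0.27 and the platelet median was 0.28 (0.317). The cell cycle median turned to 0.48 and 0.42 without replicate 2 of WT or KO at day 3 and was -0.84 and -0.80 without replicate 1, where that of ribosome biogenesis turned to -0.19 and -0.12. The immediate early call ended without replicate 2 of either (-0.02 and 0.03, with 0.323 and 0.203).

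At day 6, 1446 genes differed between KO and WT, 795 higher and 651 lower in KO. Of 30 B cell identity genes 7 were higher and 0 lower (13 higher over the list alone, median 0.42, 27 positive): Bank1, a B cell receptor scaffold, by 1.09 ± 0.139 (SE, n = 2 per group, adjusted p = 0.00517) and Cd72 by 1.04 ± 0.157 (0.00802). Fcer2a was 6.83-fold higher (2.77 ± 0.654, adjusted p = 0.0373), Cr2 4.14-fold (2.05 ± 0.29, 0.00683) and Cd40 2.27-fold (1.19 ± 0.191, 0.0101). Of 35 plasma cell genes 0 were higher and 5 lower (8 lower over the list alone, median -0.40), including Sdc1 at -1.93 ± 0.381 (adjusted p = 0.0204) and Eaf2 at -1.04 ± 0.245.

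MHC class II genes were higher in 4 of 15 (6 over the list alone, median 0.36), with Ciita, their transactivator, at 0.71 ± 0.174 and Ifi30 at 0.91 ± 0.199. Germinal centre genes were higher in 3 of 21 and lower in 2 (4 and 2 over the list alone, median 0.61), with Il21r, a receptor for T follicular help, at 1.08 ± 0.176. Marginal zone genes were higher in 5 of 22 and lower in 1 (6 and 1 over the list alone, median 0.47), and type I interferon genes changed in 0 of 45 in either adjustment (median 0.69). The camera adjusted p was 5.36e-06 for B cell identity, 0.000537 for MHC class II, 0.00444 for plasma cell, 0.0102 for type I interferon, 0.0183 for germinal centre and 0.0317 for marginal zone genes. With an estimated correlation these adjusted p were 0.406, 0.248, 0.963, 0.963, 0.248 and 0.963. Follicular genes were higher in 3 of 12 (4 higher and 1 lower over the list alone, median 0.16, adjusted p = 0.216), B cell activation genes in 5 of 39 (6 over the list alone, 0.04, 0.222) and cytokine genes in 3 of 20 (3 over the list alone, 0.03, 0.657). The cell cycle list had 0 of 69 changed in either adjustment (median -0.15, adjusted p = 0.44).

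Among markers of other cells, dendritic cell genes were higher in 4 of 21 (4 over the list alone, median 0.01, adjusted p = 0.441), with Tlr3 at 2.18 ± 0.361, and neutrophil genes in 1 of 25 (1 over the list alone, 0.66, 0.058). Erythroid, T cell and NK medians were -0.35, -0.17 and -0.19 (adjusted p = 0.149, 0.627 and 0.51), and platelet markers had a median of 0.22 although camera placed them downward (0.88). Of 35 published miR-155 targets 1 was higher and 1 lower in both adjustments (median -0.01 although camera placed the list upward, adjusted p = 0.866): Ikbke, an interferon pathway kinase, at 1.29 ± 0.223 and Sgk3 at -1.25 ± 0.227. Socs1, Spi1, Jarid2 and Inpp5d were at 0.46, 0.30, -0.45 and -0.58 (adjusted p = 0.697, 0.338, 0.314 and 0.192). The largest differences measured in both groups were Cox6a2 (11.8-fold higher), Crip3 (9.7-fold), Dleu2 (8.85-fold), Map3k6 (to 6.95% of WT), Trnp1 (7.35%) and Pgam2 (10% of WT, -3.32 ± 0.463).

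No slide held both groups. With the slide as a block 3 genes passed, 2 of them shared, among them the secreted carboxypeptidase family member Cpxm1 (-2.68 ± 0.278 without the block, -3.64 with it, adjusted p = 0.0157). The SE grew 1.67-fold, B cell identity, MHC class II and plasma cell medians were 0.41, 0.26 and -0.36, and the marginal zone and T cell medians turned to -0.09 and 0.71. Leaving out KO day 6 replicate 1 or 2 or WT day 6 replicate 1 or 2 gave 399, 155, 226 and 947 genes, keeping dim probes 629, and leaving out all day 3 arrays, chosen after seeing the data, 2796. The type I interferon median was 0.37 without WT day 6 replicate 1 (camera adjusted p = 0.118) and 0.51 without KO day 6 replicate 2 (0.182). The plasma cell median was -0.17 without WT day 6 replicate 2 (0.129) and -0.62 without replicate 1. The germinal centre and marginal zone calls ended without WT day 6 replicate 2 (0.35 and 0.49, 0.129 and 0.0913) or KO day 6 replicate 2 (0.55 and 0.47, 0.081 and 0.15).

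Averaged over the 3 days, 554 genes differed between the genotypes, 250 higher and 304 lower in KO (6 arrays against 6). Cbr1 was 4.09-fold higher (2.03 ± 0.0957, SE, adjusted p = 4.21e-05), Nmrk1 3.8-fold (1.93 ± 0.115, 0.000172), Crip3 2.72-fold and Fam177a 2.48-fold. Tmem267 stood at 24.4% and Tmem254a at 27.7% of WT (-2.03 ± 0.178 and -1.85 ± 0.0859), Nin at 36.5% and the helicase Dhx40 at 38.6% (-1.45 ± 0.0988 and -1.37 ± 0.0957).

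Of 15 MHC class II genes 2 were higher and 0 lower over all genes, and 11 higher over the list alone (median 0.32, camera adjusted p = 1.53e-06, and adjusted p = 0.103 with an estimated correlation): H2-DMb2 and H2-DMa, which edit the peptides bound to class II molecules, by 0.65 ± 0.107 and 0.32 ± 0.0686 (adjusted p = 0.0212 and 0.0443). Of 30 B cell identity genes 3 were higher (4 over the list alone, median 0.18, 28 positive, adjusted p = 1.44e-05, and 0.693 with an estimated correlation), Cd22, an inhibitory receptor, by 0.58 ± 0.0904. Interferon-gamma genes (1 of 29 higher, 3 over the list alone, median 0.39) and type I interferon genes (0 of 45 in either adjustment, 0.56) had adjusted p = 5.85e-05 and 6.75e-05 (0.834 with an estimated correlation). Plasma cell genes were lower in 3 of 35 (5 over the list alone, median -0.12, adjusted p = 0.00171, and 0.693). T cell markers were lower in 1 of 27 (2 over the list alone, median -0.41, 1.73e-05, and 0.825), the co-stimulatory receptor Cd28 at -0.94 ± 0.18, NK markers in 2 of 22 (2 over the list alone, -0.26, 0.00825, and 0.825), and the cell cycle in 0 of 69 in either adjustment (-0.27, 0.000671, and 0.855). MHC class I (0 of 23 in either adjustment, median 0.20), immediate early and heat shock (2 of 20 higher, 3 over the list alone, 0.19) and platelet genes (0 of 16 in either adjustment, 0.43) had adjusted p = 0.0134, 0.0226 and 0.0226, and 0.834, 0.693 and 0.834 with an estimated correlation. The published miR-155 targets had 0 of 35 changed in either adjustment (median 0.01, 20 positive, adjusted p = 0.907), with Spi1 at 0.38 ± 0.101 (0.0797), Socs1 at 0.46, Inpp5d at -0.14 and Jarid2 at -0.26 (adjusted p = 0.505, 0.649 and 0.372).

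Under the slide block 55 genes passed, 50 of them shared, including Cbr1 at 1.94 and Tmem254a at -1.75 (both adjusted p = 0.00604). The MHC class II, B cell identity, interferon-gamma and T cell medians were 0.23, 0.18, 0.68 and -0.13. The block ended the T cell, NK cell, platelet and immediate early calls (camera adjusted p = 0.0766 to 0.192). Leaving out 1 array gave 104 (without WT day 0 replicate 1) to 1036 genes (without WT day 3 replicate 2). Keeping dim probes gave 121. Without any day 3 array, chosen after seeing the data, 2091 genes passed. The type I interferon median was 0.19 without WT day 3 replicate 1 (camera adjusted p = 0.0777), the interferon-gamma median 0.12 (0.64 without replicate 2) and the MHC class I median 0.09 (0.363). The MHC class I call also ended without KO day 3 replicate 1 (0.12, 0.116) or WT day 6 replicate 1 (0.15, 0.0586). The cell cycle median was -0.03 and -0.04 without WT or KO day 3 replicate 2 (0.74 and 0.365), and -0.48 without replicate 1 of either. The plasma cell median was -0.21 and -0.08 without WT day 6 replicates 1 and 2, and the T cell median -0.26 without WT day 0 replicate 1. The NK call ended without WT day 6 replicate 2 (-0.20, 0.132). The platelet and immediate early calls each ended without WT or KO day 3 replicate 2 or WT or KO day 6 replicate 2, with platelet medians from 0.24 to 0.36 and immediate early medians from 0.13 to 0.23.

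The difference between the genotypes in the day 6 response passed for 51 genes, 24 with a higher and 27 with a lower change in KO. Ighg3 rose by 3.98 in WT and had a change of 0.56 in KO, a difference of -3.43 ± 0.516 (SE, adjusted p = 0.047), and Mt1, a metallothionein, 3.11 against 0.87 (-2.24 ± 0.305, 0.0297). Rfxank, a subunit of the factor that drives MHC class II genes, was at -2.31 in WT and -0.04 in KO, a difference of 2.27 ± 0.301 (adjusted p = 0.0297). Cox6a2, a cytochrome oxidase subunit, was at -2.54 in WT and 1.54 in KO (difference 4.08 ± 0.442, 0.0182) and Crip3 at -2.41 and 0.31 (2.72 ± 0.293, 0.0182), while Map3k6, a stress kinase, was at 3.07 and -0.54 (-3.61 ± 0.468, 0.0297). Of the lists, B cell identity had a higher response in KO (median 0.39, 0 of 30 changed over all genes and 3 over the list alone, adjusted p = 0.01, and adjusted p = 0.904 with an estimated correlation). The other 26 did not pass, among them plasma cell genes (-0.15, adjusted p = 0.21), MHC class II (0.16, 0.239), the cell cycle (0.25, 0.165) and published miR-155 targets (0.04, 0.44). Socs1, Jarid2, Spi1 and Inpp5d were at 0.93, -0.19, -0.46 and -0.59 (0.59, 0.824, 0.356 and 0.404).

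With slide blocked 2 genes passed, 0 of them shared, with an SE 1.73-fold as large. Ighg3 was at -4.72 (adjusted p = 0.235). The B cell identity call ended (median 0.28, camera adjusted p = 0.0696). T cell and marginal zone medians (0.47 and 0.44 without the block) were 1.64 and -0.70. Leaving out WT day 0 replicate 1 or 2, KO day 0 replicate 2, WT day 6 replicate 1 or 2, or KO day 6 replicate 1 or 2 gave 0, 17, 3, 1, 119, 0 and 0 genes, and keeping dim probes 0. The identity call also ended without KO day 0 replicate 2 (0.31).

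**Figure D2:**
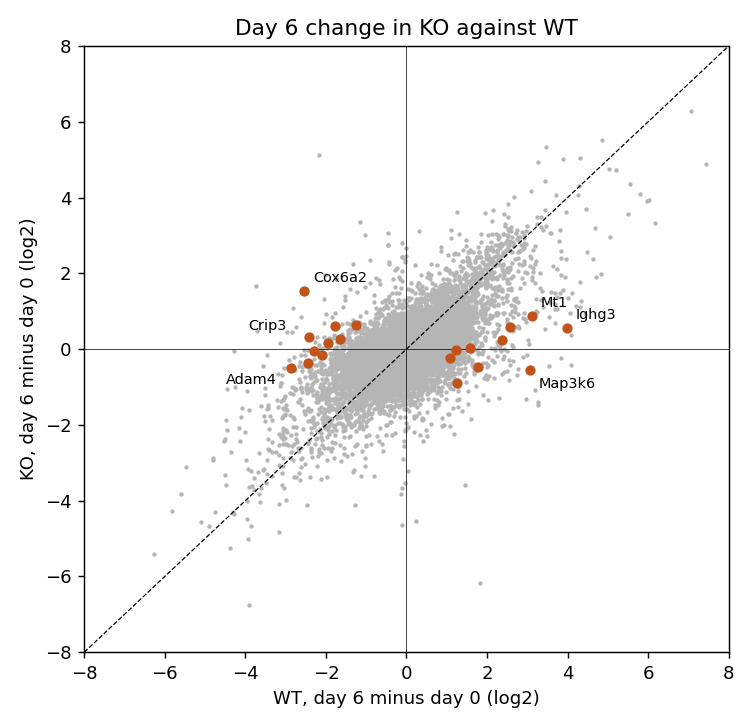
Log2 change from day 0 to day 6 in WT (x axis) and KO (y axis), each a mean of 2 arrays against 2, for all genes (grey) and 20 named genes whose difference in response passed the test (orange), with a dashed line of equal change. Ighg3 lies at 3.98 and 0.56, Map3k6 at 3.07 and -0.54, and Cox6a2 at -2.54 and 1.54.

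The difference in the day 3 response passed for 0 genes in limma (923 at an unadjusted p under 0.05). The interferon-gamma list had a higher response in KO (median 0.86, 27 of 29 positive, 0 changed in either adjustment, adjusted p = 1.62e-05, and adjusted p = 0.956 with an estimated correlation), as did NK cell markers (0.31, adjusted p = 0.029) and oxidative phosphorylation (0.18, 0.0268; both 0.956 with an estimated correlation). Socs1 had a difference of 1.87 ± 0.839 (adjusted p = 0.853), and Spi1, Jarid2 and Inpp5d were at -0.66, 0.20 and 0.13 (0.853, 0.981 and 0.986). Published miR-155 targets were at 0.19 (adjusted p = 0.0975). The lowest p belonged to Cttnbp2 and Olfr1008 (adjusted p = 0.0602 and 0.0945), both not well above background in 3 of the 4 groups. With the slide as a block the interferon-gamma, NK cell and oxidative phosphorylation medians were 1.58, 0.36 and -0.00, that of T cells turned from -0.09 to 0.74, and 0 genes passed (lowest adjusted p = 0.0686, 1524 unadjusted). Leaving out KO day 0 replicate 1 gave 15 genes, KO day 3 replicate 1 gave 3, WT day 3 replicate 1 gave 2, and WT day 0 replicate 2 or KO day 0 replicate 2 gave 1. The interferon-gamma median was 0.04 without WT day 3 replicate 1 (camera adjusted p = 0.741) and 1.71 without replicate 2. The NK call ended without WT day 0 replicate 1, KO day 0 replicate 2, WT day 3 replicate 2 or KO day 3 replicate 1 (0.29, 0.22, 0.28 and 0.23, with 0.0572, 0.288, 0.0627 and 0.0807). The oxidative phosphorylation median turned to -0.05 without KO day 3 replicate 1, was -0.00 without WT day 3 replicate 1 (0.939), and lost its call without WT day 0 replicate 2 or KO day 0 replicate 1 (0.0795 and 0.141).

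**Figure D3:**
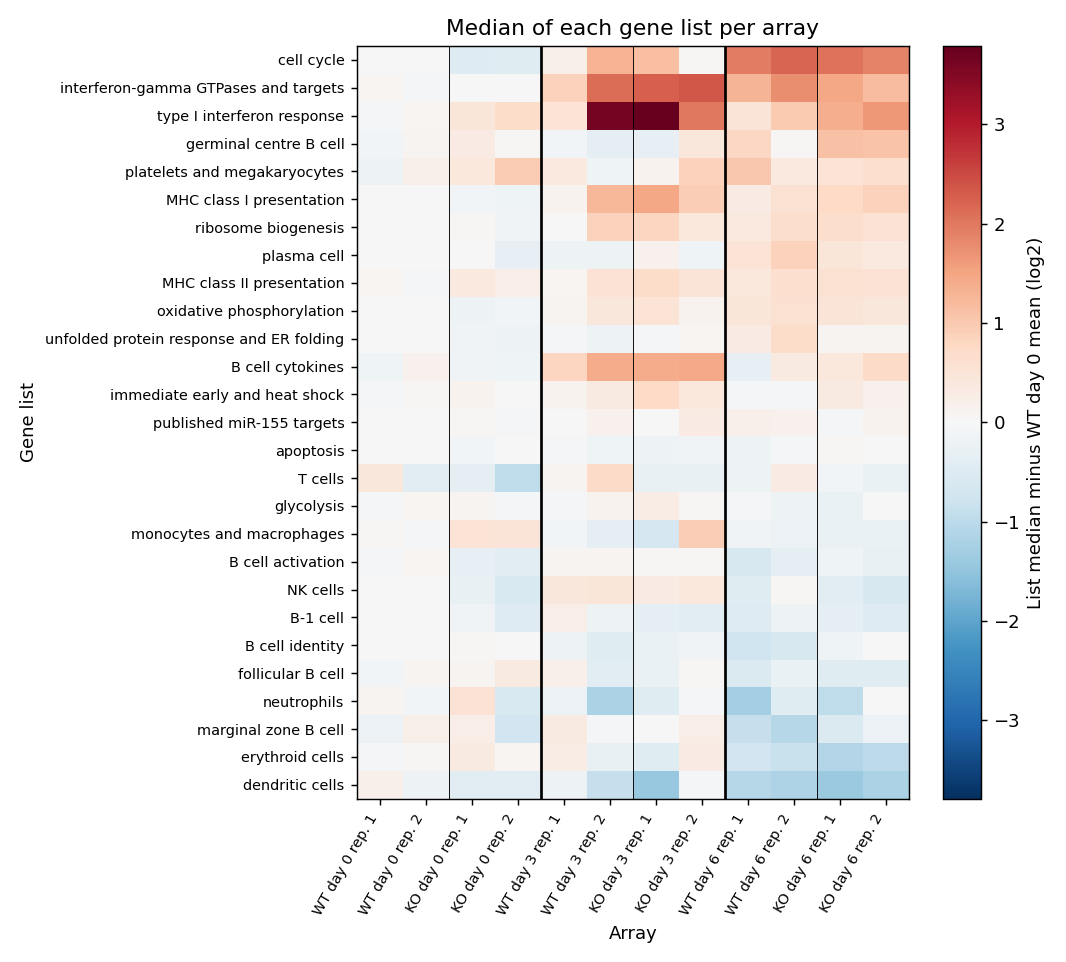
Median log2 value of each gene list on each of the 12 arrays minus the mean of the 2 WT day 0 arrays (colour scale, log2), for the lists (y axis) and arrays (x axis). Before that subtraction the cell cycle median is 1.62 to 1.95 on the day 6 arrays and at most 1.05 on the others, and the type I interferon median is 1.16 and 4.26 on the WT and 4.43 and 2.63 on the KO day 3 arrays.

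**Figure D4:**
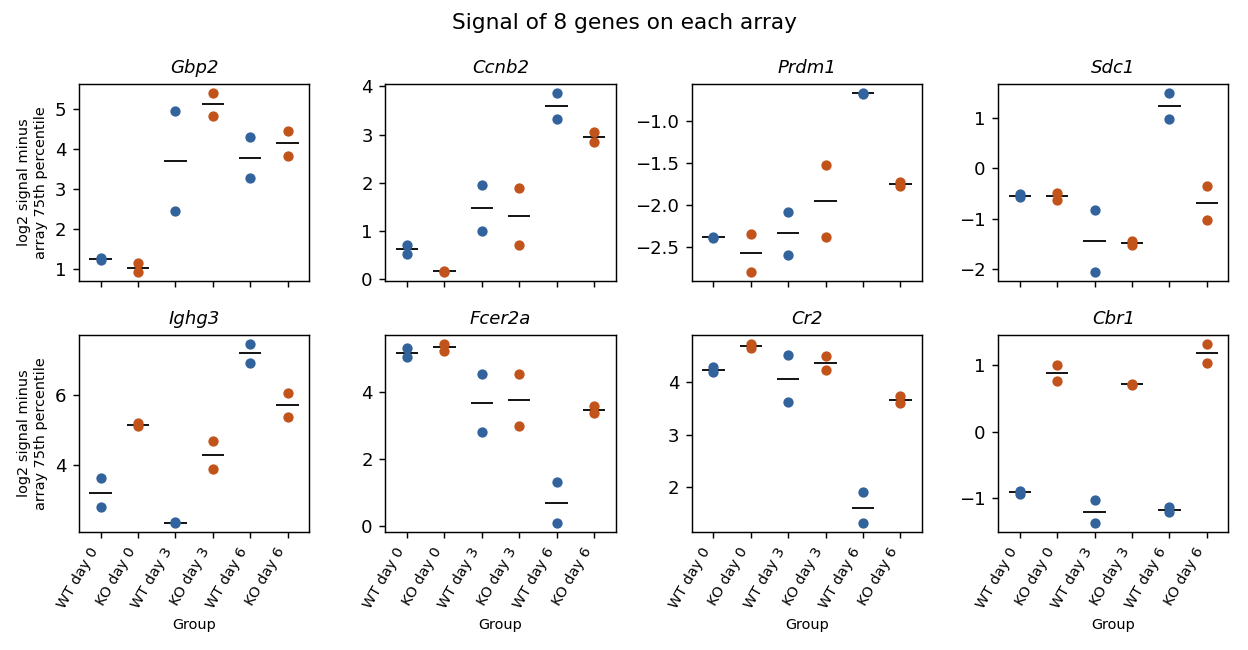
Log2 value (scaled to the array's 75th percentile, y axis) of 8 genes on each array (points) with the group mean (line), by group (x axis) and genotype (colour). Ighg3 lies at 7.46 and 6.92 in WT and 6.05 and 5.36 in KO at day 6, Prdm1 at -0.66 and -0.67 in WT and -1.78 and -1.73 in KO, and Cbr1 between 0.71 and 1.33 in all KO arrays and between -1.39 and -0.90 in all WT arrays.

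All 12 counts lay between 0 and 38 under the planned normexp background correction, which compressed dim signals on 1 array, KO day 3 replicate 2, where 9 spots had a local background over 100 and up to 329098. With those backgrounds replaced, a setting chosen after seeing the data, WT day 6 against day 0 had 3942 genes, KO day 6 against day 0 had 1931 and KO against WT at day 6 had 1115.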

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

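The test of the difference between the genotypes in the day 6 response was planned before the data were examined. It passed for 51 genes, and the 20 below are those the naming rule took, each with a mean of 2 arrays per group. A larger WT rise gave a negative difference for Ighg3 (-3.43), Map3k6 (-3.61), Mt1 (-2.24), Lrrn4cl (-2.23), Arrdc4 (-2.17), Slc23a1 (-2.14), Oscp1 (-1.99), Slc4a8 (-1.56), Imp4 (-1.34) and Scrn3 (-1.25). In WT the changes of these 10 genes lay between 1.09 (Imp4) and 3.98 (Ighg3), and in KO their changes lay between -0.91 (Arrdc4) and 0.87 (Mt1). The positive differences were Cox6a2 (4.08), Crip3 (2.72), Mia (2.39), Adam4 (2.37), Rfxank (2.27), Spice1 (2.11), Wdr78 (2.09), Mamdc4 (1.94), Acad12 (1.91) and Cbx2 (1.87), with WT changes between -2.87 (Adam4) and -1.25 (Cbx2) and KO changes between -0.50 (Adam4) and 1.54 (Cox6a2). Ighg3, the IgG3 heavy chain constant region, lay at 2.80 and 3.61 on the WT arrays and 5.11 and 5.19 on the KO arrays at day 0, a difference of 1.94 ± 0.365 that did not pass in limma (adjusted p = 0.144). With the slide as a block all 20 kept their direction and had adjusted p between 0.235 and 0.405.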

How the results depend on the processing

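The fits without the day 3 arrays and normexp with bright backgrounds replaced were chosen after the results were seen. The deposited value table gave the reported values, as it holds the same numbers. The planned lists of genes with miR-155 sites, and their alternative with longer sites alone, were not run. Signal over background limits what can be seen: 58.47% to 62.18% of spots per array were well above it, and changes between dim signals were not detectable. For every count below the cause was not tested, except where stated.

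Planned normexp gave 0 genes for WT day 3 against day 0, 38 for WT day 6 against day 0, 21 for WT day 6 against day 3. It gave 0, 1 and 2 for the same KO comparisons, 0 for KO against WT on each day, 4 averaged and 0 for the difference in day 6 response. The cause lay on 1 array: after the correction the 1st percentile of KO day 3 replicate 2 was -0.168, against -4.23 to -3.54 on the others, and -3.96 once 9 bright backgrounds were replaced. With that replacement KO day 3 against day 0 had 16 genes, KO against WT 13 at day 0 and 12 at day 3, and the average 358. Quantile normalization gave 13 for KO day 3 against day 0, 2 and 111 for the differences in day 3 and day 6 response, and put the MHC class II median for KO day 3 against day 0 at -0.38 with camera downward (adjusted p = 0.0297), where the reported median was -0.07 with camera upward (0.859). Keeping dim probes, which adds genes to the adjustment, gave 0 for WT day 3 against day 0, 2941 and 1761 for WT day 6 against days 0 and 3, 273 and 84 for KO, 5 and 629 for KO against WT at days 3 and 6, 121 averaged and 0 for the difference in day 6 response.

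The slide block, whose SE is larger by construction, gave 0, 364 and 1805 genes for WT day 3 against day 0, day 6 against day 0 and day 6 against day 3. For KO it gave 12, 0 and 41, and it gave 6, 0 and 3 for KO against WT on days 0, 3 and 6, 55 averaged and 2 for the difference in day 6 response. It turned the T cell median to -0.58 for WT day 6 against day 0, 0.71 for KO against WT at day 6 and 0.74 for the difference in day 3 response. Without the day 3 arrays KO day 6 against day 0 had 4898 genes, KO against WT 56 at day 0 and 2796 at day 6, the average 2091 and the difference in day 6 response 661. With the slide block too there were 659 for WT day 6 against day 0, 300 for KO, and 13, 59 and 12 for the last 3, with T cell medians of -0.83 (WT day 6 against day 0) and 1.22 (KO against WT at day 6). The mean of a gene's probes turned Gpi1, KO day 6 minus day 0 (-0.149), Canx, KO minus WT at day 6 (0.106), Canx, WT day 6 minus day 3 (-0.00993), and Epas1, KO minus WT averaged over days (-0.0221).

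Replicate numbers did not pair the samples: deviations of same-numbered arrays correlated over 0.1 in 3 of 15 pairs of groups (-0.56 to 0.222). A replicate block gave 0 genes for WT day 3 against day 0, 887 and 153 for KO day 6 against days 0 and 3, 5 for KO against WT at day 3, 269 averaged and 12 for the difference in day 6 response.

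Leaving out each array in turn gave 0 to 904 genes for WT day 3 against day 0, 1625 to 2401 for WT day 6 against day 0, 1153 to 3227 for WT day 6 against day 3. For the same KO comparisons it gave 5 to 45, 47 to 148 and 27 to 496, and 6 to 57, 3 to 24 and 155 to 947 for KO against WT on days 0, 3 and 6, 104 to 1036 averaged, and 0 to 15 and 0 to 119 for the differences in day 3 and day 6 response. List medians that turned sign did so mostly with a day 3 array. For KO against WT at day 3 they ranged over -0.033 to 0.67 (MHC class I), -0.84 to 0.48 (cell cycle), -0.27 to 0.63 (erythroid), -0.32 to 0.42 (glycolysis), -0.41 to 0.24 (marginal zone), -0.30 to 0.65 (monocytes and macrophages), -0.17 to 0.30 (oxidative phosphorylation), -0.19 to 0.45 (ribosome biogenesis) and -0.58 to 1.95 (type I interferon). For the difference in day 3 response they ranged over -0.41 to 0.29 (T cells), -0.43 to 0.84 (cell cycle), -0.49 to 0.73 (erythroid), -0.52 to 0.69 (monocytes and macrophages), -0.045 to 0.45 (oxidative phosphorylation), -0.21 to 0.46 (ribosome biogenesis) and -0.76 to 1.68 (type I interferon). For WT day 6 against day 3 they were -0.48 to 0.21 (MHC class I), -1.02 to 0.53 (interferon-gamma) and -0.38 to 0.19 (ribosome biogenesis), and for KO day 3 against day 0 -0.39 to 0.42 (erythroid) and -0.70 to 0.24 (monocytes and macrophages).

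Side of the threshold, and direction where a fit passed, were kept by 303 of 324 list results under quantile normalization. This held for 290 under normexp with replacement, 278 without dim filter, 310 with probe means, 319 with replicate block and 256 with slide block. Of 990 results for named genes, these numbers were 952, 905, 723, 929, 855 and 547. Of those passing in either fit, only 4 turned direction, under the mean of probes.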

Other observations

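The tests of the day 3 replicates, of the share of B cells and of the positions of genes were chosen after the results were seen, as was the fit without the day 3 arrays. Those of the slide at day 6, other probes, splits and seed matches were chosen before.

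Members of the apoptosis list moved both ways. In WT B cells at day 6, 5 of 32 rose and 5 fell against day 0 (the same counts over the list alone, median 0.16, adjusted p = 0.848): Bcl2l11 (BIM), a killer of surplus lymphocytes, rose by 1.53 ± 0.332, while Pmaip1 (NOXA) was at -1.14 ± 0.181. In KO cells 1 rose, Fas at 1.43 ± 0.246, and 1 fell, Pmaip1 at -1.13 ± 0.181 (1 and 1 over the list alone, median 0.08, adjusted p = 0.29). Bmf, also a killer, was lower in KO than WT at day 6 (-2.55 ± 0.589, adjusted p = 0.0349). Of 15 B-1 cell genes 4 rose and 2 fell in WT (4 and 2 over the list alone, median 0.31, adjusted p = 0.551) and 3 rose and 1 fell in KO (5 and 1, median 0.19, adjusted p = 0.0574). Tbx21 (T-bet), a transcription factor induced by interferon-gamma, rose by 1.20 ± 0.308 in WT and 1.70 ± 0.308 in KO.

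Of the 4576 genes that changed in WT by day 6, 83.7% went the same way in KO, with a median ratio of the KO to the WT change of 0.466. Of the 1767 that changed in KO, 92.7% went the same way in WT, with a median ratio of the WT to the KO change of 0.822. Choosing genes by one genotype's calls lowers the ratio for the other, and over all genes the major axis slope of KO on WT was 0.797.

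The replicates of each genotype at day 3 lay apart, with type I interferon medians of 1.16 and 4.26 in WT and of 4.43 and 2.63 in KO. A slide effect would carry over to the day 0 arrays on the same slides, and the slope of the day 0 on the day 3 difference was -0.0222 for WT (1698 genes, 95% interval -0.0424 to -0.00141) and 0.0299 for KO (1302 genes, 0.007 to 0.0537), where 0.5 or more had been set as the mark of a slide effect. An uninfected mouse among the day 3 samples would show day 0 levels, but the interferon-gamma list lay 1.1 above day 0 in WT replicate 1 (0.36 to 1.19) and 2.35 above it in KO replicate 2 (1.75 to 3.01). No biological explanation was tested, and a difference between mice in the pace of infection stays open.

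At day 6, 1446 genes differed between KO and WT with no slide shared between the groups. The slide 3 minus slide 1 difference at day 0 followed the day 6 change with a slope of 0.0467 (0.0229 to 0.0701, 1436 genes). Lacking spread between arrays, it argues only weakly against the slide as the whole cause. A changed share of B cells cannot be told apart from other explanations: the medians of neutrophil and erythroid markers were 0.661 and -0.349, 1.01 apart, but neither list passed camera (adjusted p = 0.058 and 0.149). The neutrophil medians of single arrays overlapped between KO (-1.34 and -0.36) and WT (-1.66 and -0.82). An effect of the genotype, a hypothesis here, and differences between mice in the course of infection stay open, and the slide block called 3 genes, 2 of them shared.

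Of the 554 genes that changed in the genotype average, 31 differed at least 2-fold between genotypes on each day by fitted values. Of these 31, 16 were higher and 15 lower in KO. With bounds for groups not well above background, 23 reached 2-fold on each day, 12 higher and 11 lower. This was not established for the others, among them Ppef2, Cxadr, Hunk, Aloxe3 and Foxp3. Igf2bp3 was at least 4.64-fold lower on each day. On chromosome 16, which carries the miR-155 gene, the mm9 probe positions were 78359501 to 78359560 (Cxadr), 90499667 to 90499725 (Hunk) and 93610497 to 93610556 (Cbr1), all 3 higher in KO by fitted values, and 5, 79 and 114 protein-coding genes lay between them and the miR-155 gene.

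Strain DNA carried along with the KO allele, or by separate breeding, may account for part of these 31 genes, since such genes would lie in clusters. Counted as loci (positions within 100 kb taken once), 10 of 27 lay within 5 Mb of another. Most of these 10 were on chromosome 11, not that of miR-155, and others on 19 and 16 (Hunk and Cbr1, not Cxadr). Of 10000 random draws 349 had 10 or more (median 4, highest 15). An earlier version counted genes, 14 of 30, which 10 of 10000 draws reached. The count of loci lies above 95% of draws and within their middle 95%, so this test leaves strain DNA open. A sequence variant under a single probe could be checked only in the 6 genes with another kept probe. In 5 of them (83.3%) another probe moved the same way by at least 0.5. The rest of the 31 genes had no other kept probe, so this explanation stays open for them. Lasting effects of the lost microRNA stay open as well.

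For the genotype average, 5 of 100 splits of arrays within days (of 108 possible, the real one included) called 554 genes or more. The highest other called 2561, so chance cannot be excluded. The 4 that called more put WT day 3 replicate 1 with KO day 3 replicate 2, both on slide 2. They kept each genotype whole at day 6, 3 of them at day 0 too. The highest joined WT day 0 with KO day 6, where a constant genotype difference cancels, and the others hold part of it. The 10 splits with that day 3 grouping and whole day 6 genotypes called 245 to 2561 genes. The 23 with it and mixed day 6 arrays called 0 to 292, and the others, the real one aside, at most 25. The slide block called 55 genes.

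One hypothesis was that transcripts with a match to the miR-155 seed rise without it. The 64 genes whose probe held AGCATTA had a median average difference of 0.0362 against 0.00588 for all genes (-0.0321 to 0.0901 over genes). This median lay at percentile 86.2 of 420 words of the same composition, and the related word GCATTAA at percentile 16. Lacking spread between arrays, the interval excludes no rise, and sites outside the probes were not tested.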
